A study of Mus musculus with 4 samples.

How the data were processed

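RNA was sequenced from 4 libraries of primary macrophages grown from C57BL/6 mouse bone marrow, all given lipopolysaccharide (LPS) after transfection with a small interfering RNA (siRNA). Per the labels, 2 libraries received Acly-E14 siRNA and 2 received control siRNA. The labels' protocols name a stranded total RNA kit and also a kit with poly(A) capture beads, so which of them enriched the RNA is not settled here. HISAT2, StringTie 1.3.0 and edgeR are named in the submitters' processing notes together with the mouse build mm10. The role of each tool, the counting program, its use of strand and the annotation are not given in the sources used here.

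The deposited table gives whole-number counts per gene and library, with no normalization per the file headers, for 34745 Ensembl gene IDs, none of them repeated. It also gives FPKM values, which the authors computed from those counts. Of 49103 FPKM values above 0 that were compared, 49103 equalled the FPKM computed from the count, a whole-number gene length and the column total within a relative tolerance of 0.001. That length was itself derived from the FPKM values, so the match shows mainly that the columns shared a length per gene. The gene lengths implied by the FPKM values equalled the merged exon length of the GENCODE M21 annotation for 2879 of 18099 genes. The gene models or the definition of gene length behind the table therefore differed from the merged exons used here. Which of these differed was not tested. Of the value columns, 1 was not used because its name carries no replicate number. Symbols came from a table of Ensembl IDs, which matched 34267 IDs, of which 17 shared a symbol with a better counted ID. IDs without a symbol held 0.153% to 0.187% of the counts per library. Coordinates are those of GENCODE M21 on mm10.

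The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), libraries were scaled with trimmed-mean (TMM) factors, and the group difference was tested with the quasi-likelihood F test without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13108 genes tested. Standard errors (SE) of log2 fold changes are those implied by the F statistic. CPM values were computed from the counts, are TMM-scaled and are given as mean ± SD over 2 libraries per group. Counting error alone is small for most genes named here, since each library held at least 21023197 counts, and intervals printed for counts cover counting error only. With 2 libraries against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333, so the tests rest on a spread shared across genes. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

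Before the data were examined, 40 gene lists were fixed. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with the rotation test fry. Camera asks whether a list moved more than the other genes, and fry whether it moved at all. Also fixed then was the rule for the genes named. It takes Acly, the 12 largest rises and the 12 largest falls among called genes with both libraries of one group beyond both of the other and a mean of at least 10 CPM in one group (predicted genes and pseudogenes left out), the 4 members of smallest p in each list described, and 14 fixed genes (among them Tnf, Il1b, Il6, Il12b, Nos2, Ptgs2, Il10, Cxcl10, Ifnb1, Arg1, Acod1 and Fasn). Some genes that meet the rule are not reported here. A gene named outside the rule is said to have been chosen after its values were seen. Lists of liver, intestinal, erythrocyte, skeletal muscle and brain genes were written after some of their genes had been seen to differ.

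The alternatives chosen at that time were the replicate number as a block, leaving out each library in turn, DESeq2's size factors (RLE) in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, library totals without TMM factors, limma on log2(FPKM + 1) with FPKM recomputed from the counts, a log2 fold change beyond 1, and an adjusted p under 0.1. A fit without the mitochondrial genome was added after the data were seen. The test was tried on counts simulated for the 13108 genes from the real means, dispersions and library sizes, with 200 genes changed. It recovered 15% of 100 genes changed by 0.5 on the log2 scale and 73% of 100 changed by 1, and called 13 unchanged genes. In the real data 4354 genes were called, 33.2% of those tested, a far larger share than was changed in the simulation. Since the adjusted p depends on that share, these recovery rates do not describe the real comparison. In a further simulation with 35 lists, a list of 30 genes was moved by 0.5 on the log2 scale. Its camera adjusted p was 9.71e-29 with the preset correlation and 0.205 with an estimated one, so the estimated version missed this shift. Genes were drawn independently there, so the simulation cannot show whether the preset p-values hold for correlated genes. In the real data the estimated correlation was 0.66 for the stromal list, 0.48 for type I interferon genes and 0.43 for cell cycle genes. Figures were drawn with matplotlib 3.10.9.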

Results

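The transcriptomes of LPS-treated mouse bone marrow-derived macrophages were compared after transfection with Acly-E14 siRNA or control siRNA, with 2 libraries per group. Acly encodes ATP citrate lyase, the cytosolic enzyme that makes acetyl-CoA from citrate. The control libraries held 21023197 and 21837806 counts, and the Acly-E14 siRNA libraries held 21323438 and 21086129. At least 1 count was present for 18730 genes. The gene with the most counts in every library was Gpnmb, with 1.72% to 1.95% of the total. Libraries of a group had Pearson correlations of log2 CPM across genes of 0.990 (control) and 0.991 (Acly-E14 siRNA), against 0.958 to 0.971 between groups. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 9.5 and 11 within the groups.

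The first question was whether the targeted gene was lower. Acly lies on the minus strand of chromosome 11 from 100476353 to 100528000 in mm10. Its level was 156 ± 2.94 CPM (SD, n = 2) in control libraries and 122 ± 5.82 CPM (n = 2) in Acly-E14 siRNA libraries. It fell by 0.35 on the log2 scale (SE 0.060, edgeR adjusted p = 0.0086), which is 0.783 of the control level, and both treated libraries lay below both controls. The adjusted p was 0.058 when control library 1 was left out. The labels do not spell out E14. In the annotation, exon 14 of the transcript Acly-203 spans 30 bases at 100503160 to 100503189 and is not part of Acly-201. Counts per gene cannot separate these transcripts, so the value is for the whole gene.

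The second question was which other transcripts differed. The 12 largest rises included the matrix genes Bgn (biglycan), Pcolce (procollagen C-endopeptidase enhancer), Ltbp2 (a microfibril-associated protein), Aebp1 and the collagen gene Col16a1. Bgn rose from 36.7 ± 14.3 to 295 ± 17.1 CPM, 8.03-fold (log2 3.01, SE 0.25). Ltbp2 rose 7.01-fold and Aebp1 6.46-fold. Fibroblast and stroma markers were higher in the same libraries, 13 of 15 of them past the threshold. The other 7 were Adam23 (11.1-fold, from 1.41 ± 0.724 CPM), Tgfbr3, Crispld2, Rasl11a, Steap4, S100a4 and Nmnat2, which rose between 6.04-fold and 8.67-fold. Tgfbr3, S100a4 and Pcolce share 297, 302 and 112 exon bases with a neighbouring gene, so their counts are less certain.

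Among the 12 largest falls was Dio2, the deiodinase that activates thyroid hormone. It dropped from 579 ± 18.7 to 40.5 ± 4.48 CPM (log2 -3.84, SE 0.092, edgeR adjusted p = 0.00011). Il23a, which encodes the p19 subunit of interleukin-23, dropped from 22.8 ± 4.44 to 4.30 ± 0.393 CPM (log2 -2.40, SE 0.18). The chemokine receptor gene Cxcr4 had a log2 change of -2.28, the adaptor gene Card14 of -3.03 and the ubiquitin ligase gene Fbxo32 of -2.10. H2-M2, a class Ib histocompatibility gene, went from 315 ± 6.48 to 69.8 ± 2.22 CPM. Dnase1l3, Rgs2, St6gal1 and Pdgfb had log2 changes between -2.02 and -1.84. The remaining 2 were mt-Nd4l, described with the mitochondrial genes, and Ube2v1. Ube2v1 is uncertain because it shares 1673 exon bases with Gm20431 and its controls were at 16.9 and 47.9 CPM. Its call was lost without either Acly-E14 siRNA library (adjusted p = 0.053 and 0.074) and with limma on log2(FPKM + 1) (0.059).

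Across all 13108 genes tested by edgeR, 2264 were higher and 2090 lower in Acly-E14 siRNA libraries, 33.2% of the genes in all. Of these 4354 genes, 2169 lay within 1.5-fold of the control level. Beyond 1 on the log2 scale, 982 genes were higher and 219 lower, so 81.8% of the large changes were rises. Higher genes made up 52.0% of calls with TMM scaling, 65.8% with library totals alone and 63.0% with limma on log2(FPKM + 1). The counts of higher and lower genes were 1175 and 982 without control library 1, 1477 and 1387 without Acly-E14 siRNA library 1, and 1045 and 1043 without Acly-E14 siRNA library 2.

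Inflammatory genes moved in both directions. Tnf, which encodes tumour necrosis factor, dropped from 3185 ± 379 to 1385 ± 163 CPM (log2 -1.20, SE 0.11, edgeR adjusted p = 0.0019). Il6 went from 542 ± 8.63 to 326 ± 15.9 CPM (log2 -0.74). In contrast, both interleukin-1 genes rose. Il1a went from 1486 ± 121 to 4797 ± 166 CPM (3.23-fold) and Il1b from 651 ± 37.8 to 1436 ± 95.7 CPM (2.20-fold). Osm, which encodes oncostatin M, rose 2.50-fold. Il12b, the p40 subunit shared by interleukins 12 and 23, rose 1.91-fold while Il23a fell.

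Of 40 tested LPS-induced cytokine and chemokine genes, 17 were higher, 11 lower and 12 not called. Adjusted over the list alone, 17 were higher and 12 lower. The list as a whole was not past the camera threshold (adjusted p = 0.28), while fry called it higher (0.037). Csf3, the gene for granulocyte colony-stimulating factor, was chosen after its values were seen. It had the largest rise of the list by fold change, from 11.6 to 68.8 CPM, while Il1a rose most in CPM. Il10 (edgeR adjusted p = 0.62), Cxcl10 (0.49) and the inducible nitric oxide synthase gene Nos2 (0.55) were not called, with log2 changes of 0.05, -0.07 and 0.05. Ptgs2, which encodes cyclooxygenase-2, rose 1.24-fold (edgeR adjusted p = 0.010), a call lost without control library 1 (0.065), control library 2 (0.054) or Acly-E14 siRNA library 1 (0.051). Of 37 targets and feedback genes of NF-kB, 11 were higher and 4 lower (camera adjusted p = 0.50, fry 0.048, up). The adhesion gene Vcam1 rose 2.36-fold, Saa3 1.74-fold, Cd83 1.56-fold and Zfp36, which encodes an mRNA decay factor, 1.31-fold. Beside the cytokine and NF-kB lists, 13 of 15 fibroblast and stroma markers were higher in the same libraries, with a list median of 1.43.

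**Figure D1:**
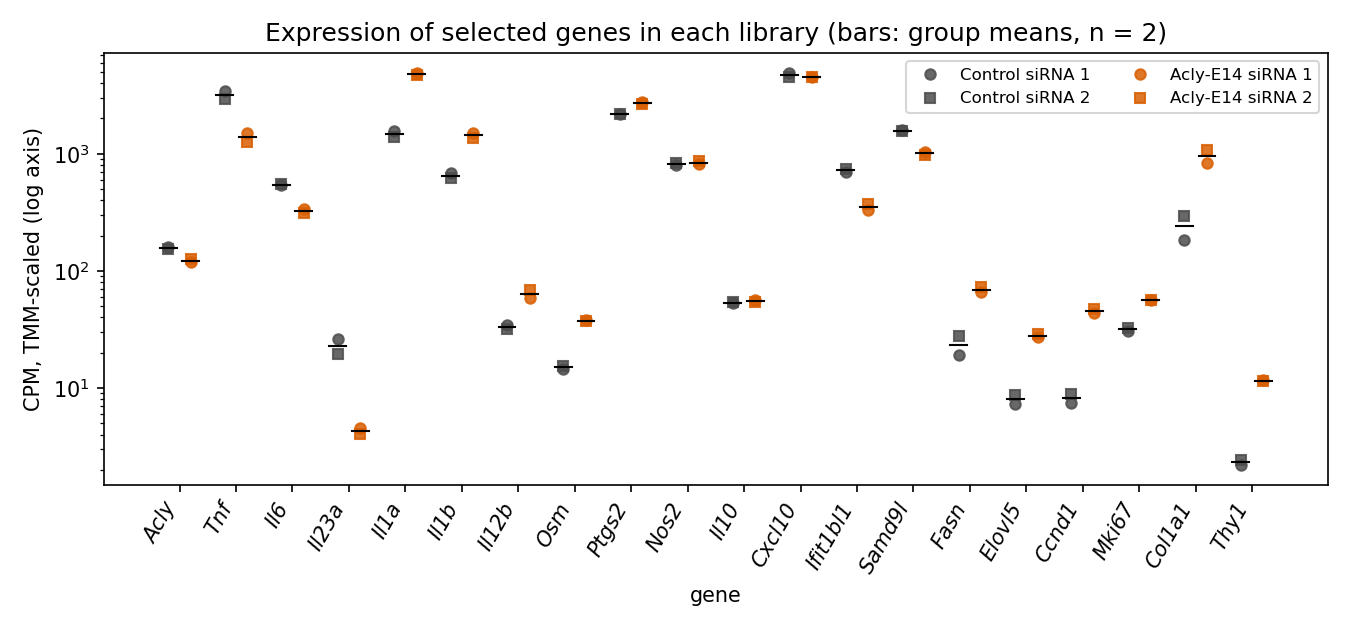
TMM-scaled CPM on a log axis for 20 genes in each of the 4 libraries. Points are single libraries and bars are group means. Tnf, Il6 and Il23a were lower and Il1a, Il1b, Osm and Il12b higher in both Acly-E14 siRNA libraries than in both controls, while Nos2 and Il10 lay close together.

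Interferon-stimulated genes were lower as a group, by modest amounts. Of 47 tested genes of the type I interferon response, 32 fell, 1 rose and 14 were not called, and adjusted over the list alone 36 were lower. The list median was -0.29 on the log2 scale (camera adjusted p = 3.7e-07, and adjusted p = 0.57 with an estimated correlation). Macrophage identity genes had a similar median in the same libraries, -0.31, with 11 of 20 lower and 4 higher. Fibroblast and stroma markers had a median of 1.43, with 13 of 15 higher. Ifit1bl1 went from 719 ± 39.6 to 350 ± 28.1 CPM (log2 -1.04, SE 0.077). Samd9l (log2 -0.64) and the RNA sensor gene Dhx58 (log2 -0.59) fell too. Rtp4 (log2 -0.48) shares 296 exon bases with Gm45338. The exception was Rsad2, which encodes viperin and was named for that reason after its values were seen. It rose from 9769 to 14041 CPM (log2 0.52). Ifnb1, the interferon-beta gene, was near 5 CPM in controls and had a log2 change of -0.73 (edgeR adjusted p = 0.043). This call was lost without any 1 of the 4 libraries (adjusted p between 0.071 and 0.21), without a filter on low counts (0.062), with library totals alone (0.064) and with DESeq2 (0.129).

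Antigen presentation by class I molecules followed the same direction. Here too, macrophage identity genes (median -0.31) were lower and fibroblast and stroma markers (median 1.43) higher in the same libraries. Of 21 tested class I genes, 13 fell and 1 rose, with a list median of -0.24 (camera adjusted p = 0.0058, and adjusted p = 0.57 with an estimated correlation). Without Acly-E14 siRNA library 2 the camera adjusted p was 0.054, and fry did not call the list (0.065). The trimming peptidase gene Erap1 had a log2 change of -0.50, H2-T22 of -0.35 and H2-M3 of -0.32, while the chaperone gene Pdia3 rose 1.47-fold. The H2-M3 call was lost without control library 1 (edgeR adjusted p = 0.058) or Acly-E14 siRNA library 2 (0.064). Reads of class I genes can be shared between near-identical family members. In the list of interferon gamma-type genes, 11 of 27 fell and 4 rose (camera adjusted p = 0.15, fry 0.037, down). Irgm1 had a log2 change of -0.49, while Gbp4, which shares exon bases with Gbp8 and Gbp9, rose 1.44-fold.

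Genes of inflammasomes and cell death were also lower on balance. Of 30 tested, 15 fell and 4 rose, with a median of -0.20 (camera adjusted p = 0.025, and adjusted p = 0.57 with an estimated correlation). Without Acly-E14 siRNA library 2 the camera adjusted p was 0.081. Members of opposite function fell together. Pmaip1 (log2 -1.40) and Bcl2l11 (log2 -0.89) encode promoters of apoptosis, and Bcl2a1d (log2 -0.49) encodes an inhibitor of it. Beside these falls, 11 of 20 macrophage identity genes were lower and 4 higher, with a median of -0.31 (camera adjusted p = 0.16). Cd68 went from 1877 ± 213 to 1172 ± 20.6 CPM and the transcription factor gene Cebpa had a log2 change of -1.18. Cd14, which encodes the LPS co-receptor, rose 2.05-fold and Apoe 1.44-fold.

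Some genes that make or modify fatty acids rose, although Acly itself fell. Of 19 tested genes of fatty acid synthesis and desaturation, 9 rose, 1, Acly, fell and 9 were not called. The list median was 0.30 (camera adjusted p = 0.039, and adjusted p = 0.57 with an estimated correlation). Fasn, the fatty acid synthase gene, rose from 23.5 ± 6.26 to 68.8 ± 4.60 CPM (2.93-fold, SE of log2 0.18). The elongase genes Elovl6 and Elovl5 rose 4.67-fold and 3.48-fold, and the desaturase gene Fads1 2.11-fold. Fibroblast and stroma markers rose in the same libraries, with 13 of 15 higher. The camera call was lost without control library 1 (adjusted p = 0.091), Acly-E14 siRNA library 1 (0.080) or Acly-E14 siRNA library 2 (0.060), without a filter on low counts (0.081) and with library totals alone (0.065), and fry did not call the list (0.067).

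Some cholesterol synthesis and uptake genes moved the same way, with 14 of 26 higher and 1 lower. Their median was 0.38 (camera adjusted p = 0.0058, and adjusted p = 0.57 with an estimated correlation). Dhcr7, which catalyses the last step of cholesterol synthesis in one of its branches, rose 3.19-fold, and Cyp51 and Hsd17b7 rose 1.62-fold and 2.08-fold. Of 31 genes of glycolysis and targets of HIF1A, 14 rose and 0 fell at an adjusted p under 0.05, while 2 were lower adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0058, and adjusted p = 0.57 with an estimated correlation). Adm (adrenomedullin) rose 3.55-fold, Ero1l 1.52-fold, the hexose transporter gene Slc2a6 1.36-fold and the lactate exporter gene Slc16a3 1.53-fold. The Slc16a3 call was lost without control library 1 (edgeR adjusted p = 0.065). As for the fatty acid genes, 13 of 15 fibroblast and stroma markers were higher in the same libraries.

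Many proliferation genes were higher. Of 38 tested cell cycle genes, 26 were higher, 2 lower and 10 not called, with a median of 0.83 (camera adjusted p = 3.7e-07, adjusted p = 0.57 with an estimated correlation, and 0.065 with fry). Ccnd1, which encodes cyclin D1, went from 8.14 ± 1.05 to 45.7 ± 2.33 CPM (5.60-fold). Mki67 rose 1.77-fold, the mitotic kinase gene Plk1 3.09-fold and the replication gene Mcm3 2.03-fold. The fibroblast and stroma markers were higher in the same libraries, by a median of 1.43 on the log2 scale.

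Markers of fibroblasts and stroma were higher in the same libraries. Of 15 tested markers, 13 were higher and 0 lower, with a median of 1.43 (camera adjusted p = 1.4e-05, and adjusted p = 0.57 with an estimated correlation). Col1a1, the collagen I gene, was at 185 and 295 CPM in the controls and at 834 and 1074 CPM in the Acly-E14 siRNA libraries. Thy1, Pdgfrb and Tagln rose 4.97-fold, 5.46-fold and 4.21-fold. All 15 were also above 1 CPM in the control mean, between 1.06 and 397 CPM.

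**Figure D2:**
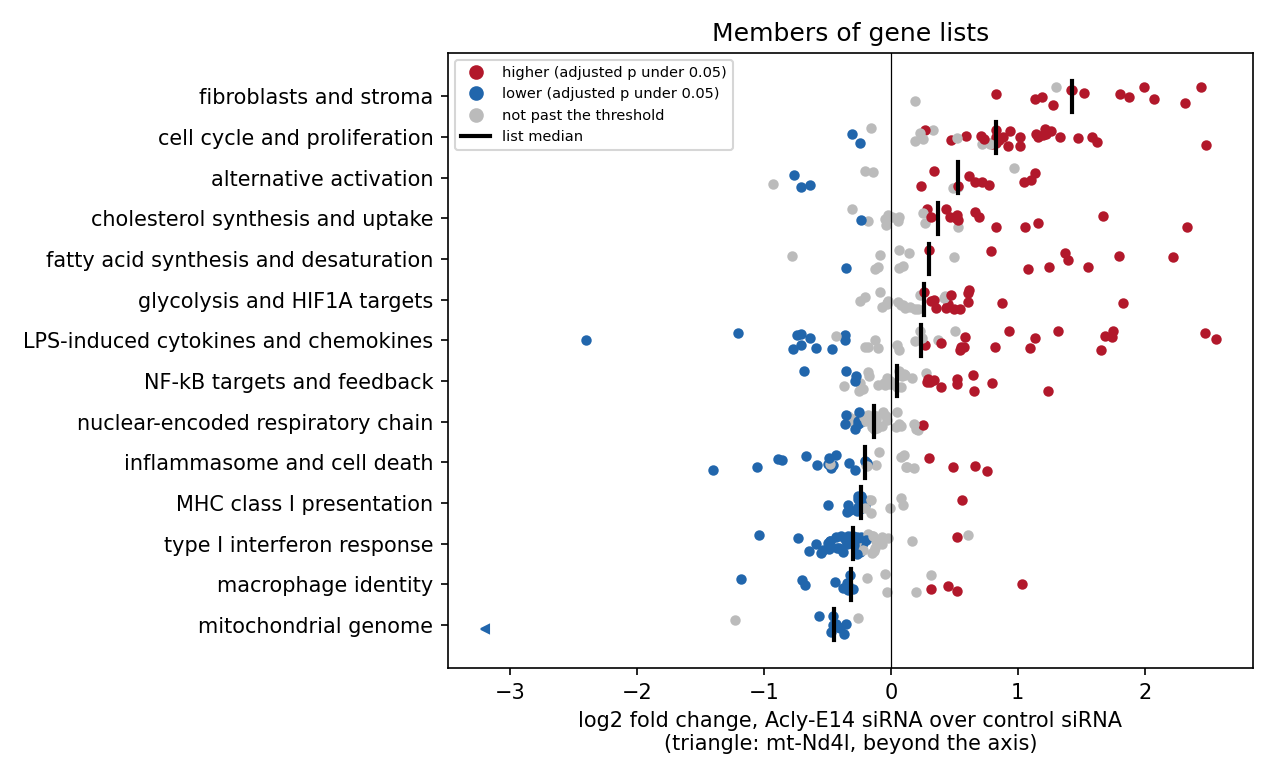
Log2 fold changes (Acly-E14 siRNA over control siRNA) of the tested members of 14 gene lists, ordered by the list median, which is the black bar. Red points are genes called higher, blue points genes called lower and grey points genes not called. Stromal and cell cycle genes lie mostly to the right, with medians of 1.43 and 0.83, and interferon genes mostly to the left, with a median of -0.29.

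Mitochondrial transcripts were lower. The mitochondrial genome took 1.82% and 1.87% of the counts in controls and 1.42% and 1.35% in Acly-E14 siRNA libraries. Of its 13 mRNAs, 11 fell and 0 rose, with a median of -0.45 (camera adjusted p = 1.5e-05, and adjusted p = 0.57 with an estimated correlation). The complex I genes mt-Nd2, mt-Nd4 and mt-Nd5 had log2 changes of -0.56, -0.45 and -0.45. One of them, mt-Nd4l (chromosome M, 9877 to 10173), stood apart, with counts of 5654 and 5814 in the controls against 1 and 1. The ratio of control over Acly-E14 siRNA was 6043, with an exact 95% interval of 1673 to 49906 that covers counting error only. It overlaps mt-Nd4 by 7 bases. In Acly-E14 siRNA library 2 alone, mt-Atp6 had 5095 counts against 30774 in library 1, and it was not called (edgeR adjusted p = 0.24). Of 36 nuclear-encoded respiratory chain genes, 7 fell and 1 rose, with a median of -0.13 (camera adjusted p = 0.039, and adjusted p = 0.57 with an estimated correlation). This camera call was lost without control library 1 (adjusted p = 0.115), Acly-E14 siRNA library 1 (0.071) or library 2 (0.088), with library totals alone (0.128) and with limma on log2(FPKM + 1) (0.230), and fry did not call the list (0.071). Cox7b had the largest change of the 4 genes named, -0.36 on the log2 scale. Uqcrc1, Cox7a2 and Uqcrq had changes of -0.26, -0.35 and -0.26, and these 3 calls were lost without any 1 of the 4 libraries (adjusted p between 0.053 and 0.11), for Uqcrc1 and Uqcrq also with library totals alone (0.055 and 0.065) and with limma on log2(FPKM + 1) (0.083 and 0.078), as was that of Cox7b without control library 1 (edgeR adjusted p = 0.066) or Acly-E14 siRNA library 1 (0.080).

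Transcripts of other tissues separated the groups at low counts. Alb, the albumin gene, had 0 and 0 counts in controls and 53 and 60 in Acly-E14 siRNA libraries. The 29 low-count genes of a liver list summed to 17 and 14 counts in controls and 192 and 175 in Acly-E14 siRNA libraries. Intestinal genes went the other way, with 181 and 216 against 11 and 9 counts for 30 genes. Among them Spink4, a goblet cell gene, had 32 and 37 counts in controls and 0 and 0 in the others. The haemoglobin gene Hbb-bs had 42 and 43 counts in controls and 0 and 1 in Acly-E14 siRNA libraries, and 9 erythrocyte genes summed to 81 and 94 against 0 and 3 counts. Skeletal muscle genes summed to 86 and 81 counts in controls and 65 and 94 in Acly-E14 siRNA libraries, and low-count brain genes to 36 and 52 against 32 and 34. Of 14 immediate early genes, which respond to handling stress among other stimuli, 6 were higher and 0 lower (camera adjusted p = 0.11). The labels give no date, lane or batch, so a difference in handling between the groups and the siRNA cannot be told apart.

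**Figure D3:**
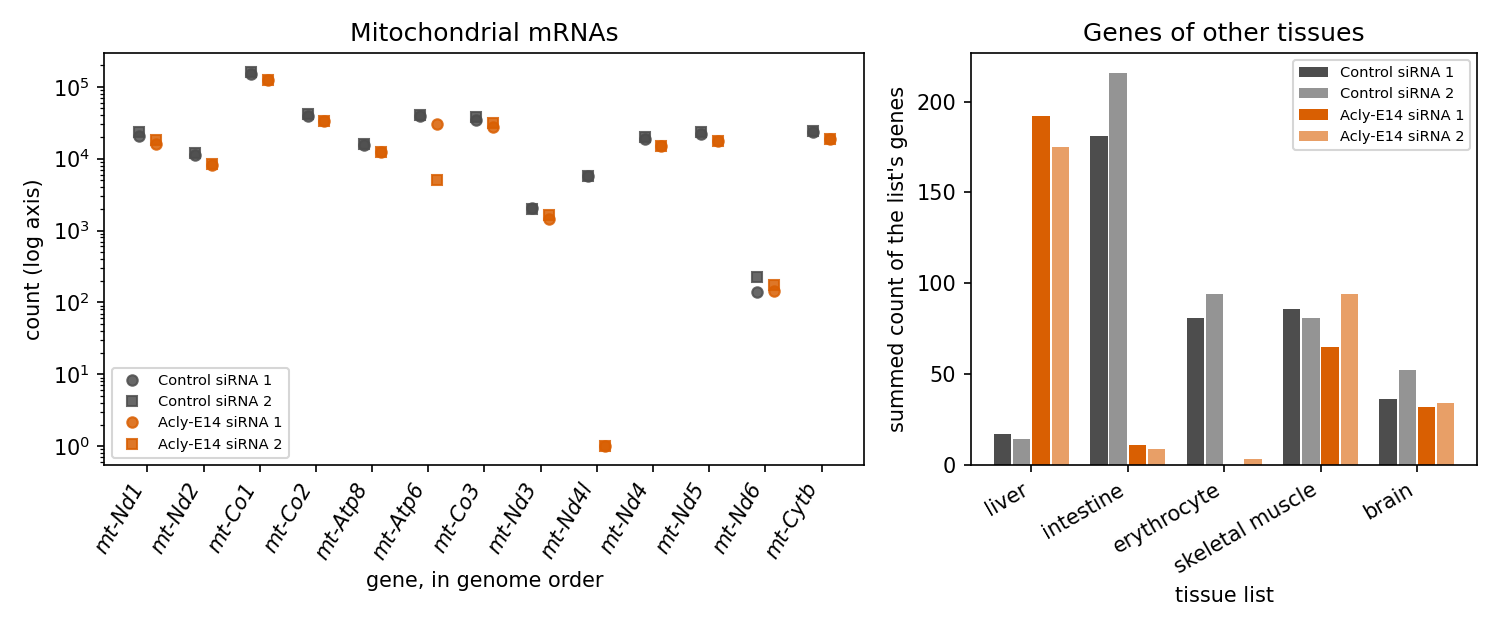
Left, counts of the 13 mitochondrial mRNAs in each library on a log axis. Right, summed counts of genes from 5 tissue lists in each library. The mt-Nd4l count was 1 in both Acly-E14 siRNA libraries, and liver genes were counted mainly in those libraries, at 192 and 175, against 181 and 216 for intestinal genes in the controls.

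Apart from the erythrocyte genes given above, markers of other blood and vessel cells did not move together. The list of erythroid and megakaryocyte genes had 2 of 6 higher and 3 lower. It was called lower by fry (adjusted p = 0.0080) but not by camera (0.23). Of 4 tested neutrophil genes, 2 were higher and 1 lower. The S100a8 call (higher, edgeR adjusted p = 0.043) was lost without control library 1 (0.083), control library 2 (0.153) or Acly-E14 siRNA library 2 (0.216), with a replicate block (0.052), without a filter on low counts (0.082) and with DESeq2 (0.067). S100a9 went from 1.23 ± 0.155 to 0.0915 ± 0.0648 CPM and Csf3r rose 1.45-fold. Of 9 dendritic cell genes, 0 were higher and 1, Cd24a, was lower (log2 -0.81). Among 3 B cell genes Igkc was lower, from 2.31 ± 0.311 to 0.251 ± 0.0967 CPM. Igkc (42 and 54 counts in controls against 4 and 7) and S100a9 (27 and 24 against 3 and 1) had the same direction as the intestinal and erythrocyte genes. Whether they too reflect RNA or reads from other material in the controls was not tested. Of 4 endothelial genes, 1 was higher and 2 lower, but without Acly-E14 siRNA library 2 this became 0 higher and 1 lower. The Eng call (higher) was then lost (edgeR adjusted p = 0.087), as it was without control library 2 (0.072). The Cdh5 call (lower, 0.049) was kept without control library 2 but lost without each of the other libraries (adjusted p between 0.114 and 0.179), with a replicate block (0.056), without a filter on low counts (0.079), with library totals alone (0.091), with DESeq2 (0.121) and with limma on log2(FPKM + 1) (0.075). With a replicate block, Esam, Dpp4 of the dendritic cell list and Gata2 of the mast cell, basophil and eosinophil list were called higher. Ighm of the B cell list was called lower (edgeR adjusted p between 0.029 and 0.040 for these genes). In the main test, 0 of the 3 tested mast cell, basophil and eosinophil genes were higher and 1 lower. Esam was also called without control library 2 (0.0498) and Dpp4 without Acly-E14 siRNA library 1 (0.031). Kdr, a receptor for vascular endothelial growth factor, went from 273 ± 6.00 to 100.2 ± 3.65 CPM.

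Genes that use acetyl-CoA or set histone acetylation, the processes downstream of ATP citrate lyase, mostly did not pass the test. Of 35 tested, 2 were higher, 7 lower and 26 not called, with a median of -0.10. The list was not past the camera threshold (adjusted p = 0.28) but was called lower by fry (adjusted p = 0.0080). The deacetylase gene Sirt1 had a log2 change of -0.79, the acetyltransferase gene Kat2b of -0.72 and the bromodomain gene Brd2 of -0.58, while Hdac7 rose 1.85-fold. Of 38 genes of Toll-like receptor signalling, 10 were lower and 2 higher (camera adjusted p = 0.055). Its members Tlr4, Tlr7 and Mapk14 differed by more than 2-fold between libraries of a group and were not called. Tlr9, the receptor for unmethylated DNA, went from 55.6 ± 1.72 to 19.2 ± 0.736 CPM, and Tab2 and Tollip had log2 changes of -0.70 and -0.53. Acod1, which makes itaconate, had a log2 change of -0.22 (edgeR adjusted p = 0.038), lost without any 1 of the 4 libraries (adjusted p between 0.087 and 0.19), with library totals alone (0.078) and with limma on log2(FPKM + 1) (0.136). Arg1 was at 9.92 ± 4.69 and 5.21 ± 1.29 CPM and was not called (edgeR adjusted p = 0.095). Arg1 was called without control library 1 (adjusted p = 0.031) and with a replicate block (log2 -0.89, adjusted p = 0.015), being higher in library 2 than in library 1 of both groups (6.61 and 13.2 CPM in controls, 4.30 and 6.12 CPM after Acly-E14 siRNA).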

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

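Of the alternatives, only the fit without the mitochondrial genome was chosen after the data were seen. Acly had a negative log2 fold change under all 11 alternatives, from -0.40 to -0.25. Leaving out 1 library gave -0.40 to -0.30, with the adjusted p at 0.058 without control library 1 and under 0.05 otherwise. The lone library of a group was then assumed to vary like the other group. Leaving out 1 library gave 1045 to 1815 higher and 982 to 1400 lower genes in place of 2264 and 2090, and 6 to 11 lists past the camera threshold in place of 10, with fewer samples in each fit. Of the 166 other named genes that edgeR called, 135 stayed past the threshold without each library, as did 6 of the 10 lists. Most of these genes were named for a large change or a small p in the same data, so the share that stayed does not stand for all called genes. No named gene or list called in the main comparison or an alternative changed direction. A log2 fold change beyond 1 left 982 higher and 219 lower genes. Limma on log2(FPKM + 1) called 1266 lower genes. It used library totals without TMM factors, and 63.0% of its calls were higher, against 65.8% with library totals alone and 52.0% with TMM. Its other differences, such as the 9585 genes tested, were not separated from this. On the log2(FPKM + 1) scale the mean correlation within groups was 0.995 in place of 0.991. Library totals alone moved the median log2 fold change from 0.00 to 0.09, with 2776 higher and 1446 lower genes. With an estimated correlation 0 lists passed camera, the smallest adjusted p being 0.57, while 15 passed the directional fry test, 6 of them shared with camera. Over all tested genes, libraries with the same number shared little (correlation of deviations 0.14 over 2 pairs). Some genes, such as G530011O06Rik, Col1a1 and Arg1, did differ alike between numbers 1 and 2 in both groups. The labels tie the numbers to nothing shared, so the main test did not treat them as pairs, and pairing is not excluded. A replicate block gave 2514 higher and 2382 lower genes and 11 lists. Without the mitochondrial genome there were 2265 higher and 2081 lower genes. Depth limits genes near 1 CPM or below, such as S100a9. Alternatives meant for tables without counts did not apply.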

Other observations

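The tests of mt-Nd4l, of genes from other tissues and of stromal RNA in this part were chosen only after their results had been seen. Lysosomal genes moved both ways. Of 29 tested genes of lysosomes and autophagy, 14 were lower and 5 higher (camera adjusted p = 0.066). The protease gene Ctsk went from 669 ± 45.9 to 247 ± 18.2 CPM and the proton pump subunit gene Atp6v1a had a log2 change of -0.79. Lipa, which encodes the acid lipase that frees cholesterol from its esters, rose 2.73-fold, and Gusb rose 1.61-fold. Surface receptors also parted, with 7 of 29 phagocytic and scavenger receptor genes higher and 9 lower (camera adjusted p = 0.66). Clec7a, the beta-glucan receptor gene, rose 2.20-fold and Olr1 rose 2.17-fold, while Clec4n had a log2 change of -2.15. Itgb2, the beta 2 integrin gene, dropped from 1404 ± 54.7 to 518 ± 24.2 CPM (log2 -1.44, SE 0.063).

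Lipid handling apart from synthesis moved both ways. Of 21 genes of fatty acid oxidation and PPAR, 8 were lower and 3 higher (camera adjusted p = 0.16). The lipid chaperone genes Fabp4 and Fabp5 and the fatty acid receptor gene Cd36 had log2 changes of -1.29, -0.45 and -0.46, while Angptl4 rose 2.75-fold. Of 16 LXR targets and efflux genes, 7 were higher and 5 lower (camera adjusted p = 0.63), with Abcg1 at -0.57 and Apoe at 0.52 on the log2 scale. Among 28 genes of NRF2 and oxidative stress, 9 were lower and 5 higher (camera adjusted p = 0.075). The pentose phosphate genes Taldo1 and Pgd had changes of -0.66 and -0.56, and Nqo1 rose 3.22-fold. In the tricarboxylic acid cycle, Sdhb had a log2 change of 0.58, with 5 of 29 genes in each direction (camera adjusted p = 0.88). Of 25 genes of migration, 8 were higher and 9 lower (camera adjusted p = 0.50). The protease inhibitor genes Timp1 and Timp2 rose 5.52-fold and 2.59-fold, and the collagenase gene Mmp13 had a change of -0.68. Of 19 genes of alternative activation, 10 were higher and 3 lower (camera adjusted p = 0.11, fry 0.048, up). Il4ra, a receptor chain for interleukin-4, rose 2.16-fold, and the mannose receptor gene Mrc1 had a change of -0.63. Of 20 genes of the unfolded protein response, 9 were higher and 1 lower (camera adjusted p = 0.074, fry 0.033, up), and of 41 splicing factor genes 4 were higher and 7 lower (camera adjusted p = 0.53, fry 0.00995, down).

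The near absence of mt-Nd4l from both Acly-E14 siRNA libraries is hard to place, since mt-Nd4l and mt-Nd4 are carried on the same RNA. The change of mt-Nd4 differed by -0.018 on the log2 scale from the median of the other mitochondrial mRNAs, which argues against a loss of the shared RNA. It also argues against reads assigned to mt-Nd4 in place of mt-Nd4l, which would have raised mt-Nd4 by 0.37. Reads left out by the counting where genes overlap remain a candidate only if the counting acted differently between libraries. The overlap is the same in every library, and mt-Nd4l had 5654 and 5814 counts in controls, which argues against a rule applied alike. Of the 13 mitochondrial mRNAs, 5 overlap a neighbour on the same strand. The 2 out of line by more than 2-fold in a library, mt-Nd4l and mt-Atp6, are among these 5. The others, mt-Nd4, mt-Atp8 and mt-Co3, were in line in every library. For mt-Atp6, the libraries given the same Acly-E14 siRNA differed (30774 and 5095 counts), which the siRNA alone does not account for. Since 2 genes are too few to decide, 2 explanations of mt-Nd4l cannot be told apart. They are counting that differed between libraries and an siRNA effect on mt-Nd4l that left mt-Nd4 in line.

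Liver transcripts in the Acly-E14 siRNA libraries and intestinal ones in the controls may be RNA or reads from other material handled with each group. Of 29 low-count liver genes, 16 had counts in both Acly-E14 siRNA libraries and 0 in both controls, against at most 8 in 10000 random lists matched on total count. A general rise of genes of other tissues is argued against by the summed counts of skeletal muscle and brain genes. Their ratio of Acly-E14 siRNA over control was 0.892 (exact 95% interval 0.742 to 1.07). Single muscle genes moved both ways, so the sum does not show that each was unchanged. Mylpf had 3 and 11 counts in controls against 22 and 24, and Smpx 12 and 10 against 0 and 0. Of 30 intestinal genes, 13 had counts in both controls and 0 in the others, against at most 4 in random lists. This fell short of the share of the list set as the criterion, so intestinal RNA or reads stay open there. The goblet cell gene Spink4 was among the 13, while abundant genes of absorptive cells such as Fabp1 had 0 counts. Trf was left out of the liver list for its high counts in macrophages, Hpx and Rbp4 also had counts in controls, and the lists held genes already seen to differ.

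Stromal genes were higher together with some lipid synthesis, cell cycle and cytokine genes, and whether more stromal RNA accounts for this could not be decided. Col1a1 was higher in library 2 than in library 1 of both groups (185 and 295 CPM in controls, 834 and 1074 CPM after Acly-E14 siRNA). Not every marker followed it after Acly-E14 siRNA. Tagln did (77.7 and 107 CPM in libraries 1 and 2), while Thy1 (11.6 and 11.5) and Pdgfrb (23.9 and 24.7) hardly differed. The difference between replicates, summed as CPM so that abundant genes weighed most, was used to predict how other genes would move with stromal RNA. This predicted 106% of the observed CPM rise of the 9 fatty acid genes called higher (95% bootstrap interval over genes, not libraries, 62.7 to 154), 52.9% for 14 cholesterol genes (-0.00 to 100.4), 74.4% for 26 cell cycle genes (48.4 to 102) and -19.8% for the 17 cytokine genes called higher (-33.2 to 28.4). Random sets of 9 other genes called higher gave -55.8% to 111% (95% range), and sets of 17 gave -51.8% to 102%, so the prediction does not set these lists apart, and Il1a alone made up 3311 of the 4968 CPM of the cytokine rise. Stromal RNA and an effect of the siRNA in macrophages both stay open for these genes, and neither was tested for the glycolysis genes or for matrix genes such as Bgn.

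A few well-counted genes differed sharply between replicates. Of 3897 genes with at least 1000 counts in a library, 47 differed by more than 2-fold between the libraries of a group. They include Mob1a, with 9721 and 9308 counts in controls and 8663 and 1977 in Acly-E14 siRNA libraries, and the LPS receptor gene Tlr4, with 251, 337, 263 and 1348. In G530011O06Rik the library numbers agreed across groups, with 1653 and 226 counts in controls 1 and 2 and 1178 and 149 in Acly-E14 siRNA libraries 1 and 2. These 3 genes were chosen after their values were seen.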
